A study of Mus musculus with 2 samples.

How the data were processed

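Gene expression was measured in pancreatic islets of adult mice on Affymetrix microarrays, with 1 array for littermate control islets and 1 array for islets of mice carrying a beta cell-specific deletion of Zbtb20, a gene for a zinc finger transcription factor. Per the labels, the mice were 2 to 3 months old and of mixed background. Islets were freed with collagenase, picked by hand, cultured overnight and frozen. Biotin-labelled cRNA was made from 6 µg of Trizol-extracted RNA. The labels do not say how many animals contributed to an array.

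The deposited values are linear probe set intensities (MAS5 signals), with MAS5 named in the submitters' processing notes and its version not given in the sources used here. MAS5 is the Affymetrix algorithm that summarises the perfect match and mismatch probes of a probe set into 1 signal. The table held 45037 probe sets for each array and no probe sets named as Affymetrix controls. Intensities in the deposited table ran from 0.1 to 15324 in the control and from 0.1 to 14244 in the knockout-labelled array. The medians were 21.6 and 21.7, and the means after trimming 2% at each end were 99.3 on both, as on arrays brought to a common scale. The scaling target, the background step and the detection calls were not given in the sources used here. The intensities were used as deposited, with no further normalization.

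Genes were assigned through the platform annotation supplied with the table, which is dated and can carry old names. It paired 34945 probe sets with 1 gene, 932 with several and left 9160 unnamed. Of the probe sets with 1 gene, 34741 matched a gene of the RefSeq table for GRCm38.p6 by Entrez identifier, and no symbol changed. Only probe sets with 1 gene named a gene, giving 18193 genes. A gene was represented by its brightest probe set, the one with the highest mean log2 signal over both arrays.

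Since there were no detection calls, the 50th percentile of each array served as a floor. Signals under it were raised to it before the log2 ratio of knockout-labelled over control was taken. Genes under the floor on both arrays were left out. This left 11802 genes, of which 10450 were above the floor on both arrays. For the 1352 genes above it on 1 array only, the ratio is a bound and is written as "at least". The floor is not a detection limit, and a signal just above it can still be background.

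With 1 array per group there are no replicates, so no p-value, standard error or adjusted p can be given, and every ratio compares 2 RNA preparations. A gene was counted as higher or lower from a 2-fold ratio on. As the only available guides to measurement error, the spread of log2 ratios among different probe sets of 1 gene (median SD 0.21 over 4719 genes) and the spread across genes of similar signal were computed. Probe sets of 1 gene share the RNA and the array, so they leave out all variation between animals and preparations.

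Before the data were examined, 41 gene lists with 794 symbols were fixed for islet cell types, metabolism, secretion, stress, growth and the other cell types an islet preparation can hold. A 1-gene probe set was found for 711 of the symbols, 12 of them through a synonym. The other 83 were not analysed here. The median log2 ratio of each list with at least 4 measured genes was set against 10000 random lists of the same size. Each random gene was drawn with replacement from the same 1 of 20 bins of mean signal. A list was said to stand apart when its median lay below the 2.5th or above the 97.5th percentile, which is a description of these 2 arrays and not a test of genotype.

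The rule for the genes named in the text was also fixed beforehand. It takes Zbtb20, the 12 largest ratios in each direction among genes above the floor on both arrays, the 5 largest bounds in each direction, 12 preset islet genes, and up to 4 members of each list by size of ratio. Preset genes with no 1-gene probe set in the annotation used, such as Ins1 and Mafa, were not analysed here. Genes named outside this rule are said to be so.

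The procedure was tested on simulated data. The observed log2 ratios were shuffled within bins of signal, which keeps the real changes in the noise, and 200 genes were given a known fold change in the 1-against-1 comparison. Over 11833 genes, 98% of genes with a planted 4-fold change and 46% of those with a planted 2-fold change were called at 2-fold. Of the genes with no planted change, 3.07% were called. Because the observed ratios were reused, this share follows the observed ones (1.82% higher and 1.44% lower). It is not a rate of false calls. A planted 2-fold change equals the calling limit, so its share of 46% reflects noise around that limit. Of 200 unchanged lists of 15 genes, 5.5% stood apart, as did 98% of 100 lists shifted by 0.4 on the log2 scale. Both kinds of list held genes drawn at random, so these shares do not cover lists whose genes vary together.

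The alternatives tried were division by the array median, quantile normalization, loess of the ratio on the mean signal (span 0.3), floors at the 30th and 70th percentile, no floor with a pseudocount of 16, the mean over all probe sets of a gene, removal of probe sets with the suffixes _x_at and _s_at, limits of 1.5-fold and 3-fold, list means in place of medians and random lists not matched on signal. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.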

Results

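The study asked which genes depend on the transcription factor ZBTB20 in pancreatic beta cells. It compared islets of adult mice lacking Zbtb20 in beta cells with islets of littermate controls on 1 microarray each. Islets are clusters of endocrine cells in which insulin-producing beta cells lie beside glucagon-producing alpha cells, delta cells and PP cells, so the arrays measured a mixture of cell types. Log2 signals of the 10450 named genes above the floor on both arrays correlated between the arrays with r = 0.97, a correlation across genes, which are not independent replicates. All ratios below are knockout-labelled over control, without replicate error, and none was tested for significance.

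The targeted gene was examined first. Zbtb20 was represented by 9 probe sets, and they did not move together. The signal was lower in the knockout-labelled islets for 5 of them and higher for 4, with a median log2 ratio of -0.062 (SD 0.45 among the 9 probe sets). The ratio farthest from 1 was that of probe set 1443471_at, from 99.8 in the control to 54.7, a 1.82-fold lower signal. The brightest probe set, 1437598_at, gave 238 and 205. In the other direction, 1422064_a_at went from 100.3 to 146. Which part of the gene was deleted is not given in the sources used here, and a probe set outside it would not register the deletion. Islet cells other than beta cells also keep the gene. The Zbtb20 signals therefore neither bear out nor contradict the genotype label, and the array is called knockout-labelled throughout.

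**Figure D1:**
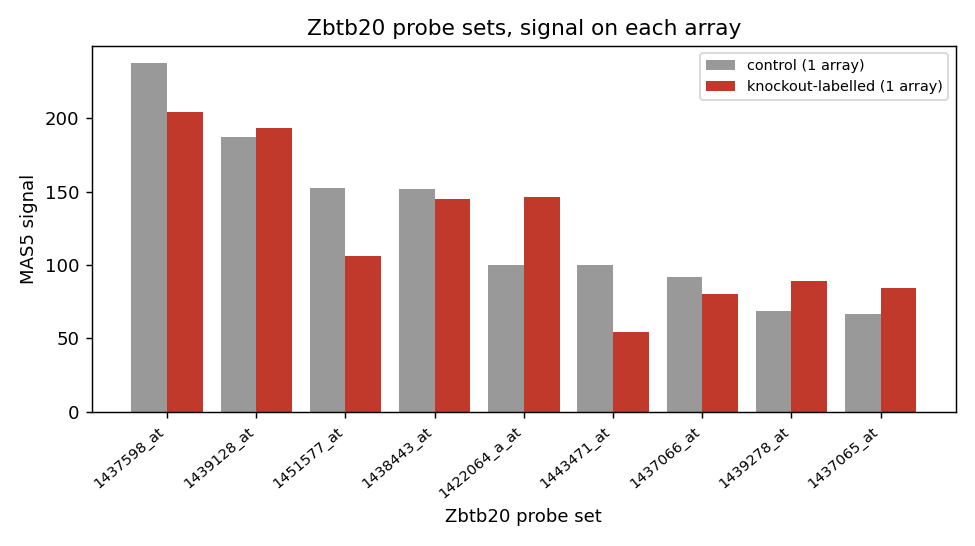
MAS5 signal (linear axis from 0) of the 9 Zbtb20 probe sets in control islets (grey bars) and knockout-labelled islets (red bars), 1 array each and so without error bars. The signal is lower in the knockout-labelled array for 5 probe sets and higher for 4.

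Across the genome, Fbp1, which encodes the gluconeogenic enzyme fructose-1,6-bisphosphatase, showed the largest ratio of all genes above the floor on both arrays. Its signal was 241 in control and 4333 in knockout-labelled islets, 18.0-fold higher. It was followed by Aldh1a3, a retinaldehyde dehydrogenase (14.6-fold, from 22.2 to 324), Crispld2 (12.1-fold, from 92.9 to 1124), the peptide hormone gene Cck (11.6-fold, from 23.5 to 273) and the neuropeptide gene Npy (11.4-fold, from 118 to 1340). In the opposite direction the largest ratio was that of Reg2, a member of the Reg family of secreted lectins, which was 9.47-fold lower (from 725 to 76.6). The chemokine gene Cxcl1 was 4.79-fold lower and Reg3b was 4.37-fold lower.

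The other 7 of the 12 largest ratios above 1 belonged to the water channel gene Aqp4 (7.70-fold), the cytokine receptor subunit gene Csf2rb (7.61-fold), Rasgrp1 (6.22-fold), the trypsinogen gene Prss3 (5.92-fold), the prostaglandin E receptor gene Ptger4 (5.73-fold), the mannose receptor gene Mrc1 (5.34-fold) and Cdc14a (5.13-fold). Cdc14a, Aldh1a3, Cck and Mrc1 had control signals of 21.9, 22.2, 23.5 and 24.5, next to the floor of 21.6. Cdc14a and Aldh1a3 each had 2 other probe sets, none above the floor on both arrays. Prss3 has close paralogs, and its probe set can take up their transcripts. On the lower side stood Slc12a7 (3.99-fold lower), the tachykinin receptor gene Tacr3 (3.79-fold), Prss23 (3.60-fold), the small heat shock protein gene Hspb8 (3.46-fold), Dapl1 (3.42-fold), Diras2 (3.28-fold), the chemokine gene Cxcl5 (3.27-fold), Prap1 (3.20-fold) and the surface protein gene Prom1 (3.03-fold). Hspb8 had another probe set that went the other way, with a log2 ratio of 0.18. Slc12a7 had a knockout-labelled signal of 23.9, next to the floor of 21.7 on that array. Its 1 other probe set was not above the floor on both arrays. Other measured probe sets of Crispld2 gave log2 ratios of 3.09 and 3.63, those of Aqp4 1.48 and 3.19, and that of Csf2rb 2.37, whereas those of Cxcl1 gave smaller values of -0.96 and -0.27. Fbp1, Cck, Npy and Reg2 had a single probe set.

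Several genes were above the floor on 1 array only. Ptger3, another prostaglandin E receptor gene, was at least 21.1-fold higher in knockout-labelled islets, with a signal of 455. Adgrg6 was at least 12.2-fold higher, Gfra1, which encodes a receptor for the growth factor GDNF, at least 7.06-fold, Slc5a10 at least 6.68-fold and A930009L07Rik at least 6.29-fold. The largest bounds on the lower side were smaller, at least 3.24-fold for Reg3d, 3.18-fold for the granulocyte growth factor gene Csf3, 3.07-fold for Rab15, 2.84-fold for decorin (Dcn) and 2.81-fold for Qpct.

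In all, 215 genes (1.82% of 11802) were at least 2-fold higher and 170 (1.44%) at least 2-fold lower. A 4-fold difference was reached by 33 genes on the higher side and by 3 on the lower side. Of the 56 higher genes that had another measured probe set, 50 had all other probe sets above 1 and 26 had all of them at 2-fold or more. For the lower genes these numbers were 45, 36 and 12. The spread of the ratios depended on the signal. The central 95% of genes with a mean signal up to 67 ran from -0.996 to 0.975 on the log2 scale, and for signals between 300 and 1000 from -0.58 to 0.64, so a 2-fold ratio of a weak gene lies near the edge of the spread. With the floor at the 70th percentile, 96 genes were higher and 64 lower.

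**Figure D2:**
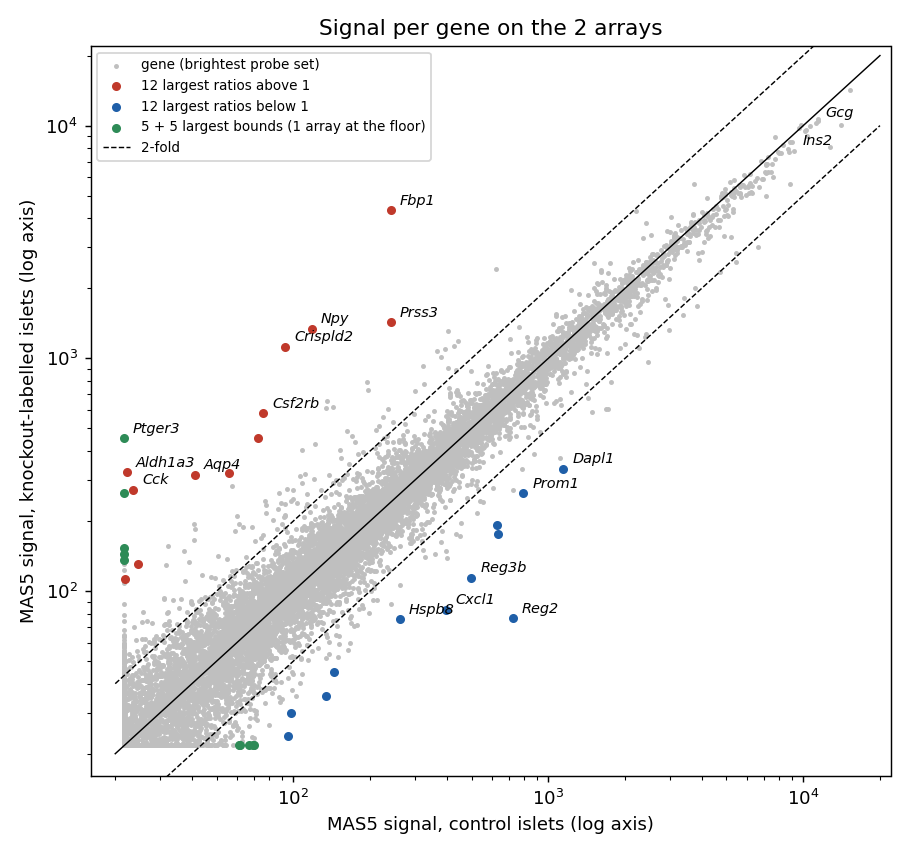
MAS5 signal per gene in control islets (x, log axis) and knockout-labelled islets (y, log axis), 1 array each, for the 11802 genes above the floor on 1 or both arrays, with signals under the floor drawn at the floor. The solid line marks equal signals and the dashed lines 2-fold. Fbp1 lies farthest above the line among genes above the floor on both arrays, at 241 and 4333, and Reg2 farthest below, at 725 and 76.6.

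The endocrine hormone genes were at similar and very high signals on both arrays. Ins2 (insulin) was 9194 in control and 7786 in knockout-labelled islets, Gcg (glucagon) 11215 and 10292, Sst (somatostatin) 9661 and 9770 and Iapp (amylin) 15324 and 14244. Signals at this height can be compressed. Another, weaker Iapp probe set went the other way, with a log2 ratio of 0.85. Ppy (pancreatic polypeptide) differed more, at 12702 and 8095, 1.57-fold lower. The list of islet hormones and secreted peptides had 2 of 15 measured genes at least 2-fold higher, Npy and Nnat (log2 ratio 1.53), and none 2-fold lower. Its median of -0.11 lay within the range of random lists.

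Genes of the mature beta cell were likewise within 2-fold. None of the 18 measured genes of that list reached 2-fold and its median log2 ratio was -0.053, at the 35.0th percentile of random lists. Slc2a2, the main glucose transporter gene of mouse beta cells, was 276 in control and 396 in knockout-labelled islets. G6pc2, an islet glucose-6-phosphatase subunit, was 6256 and 5168. The prohormone convertase gene Pcsk1 had a log2 ratio of 0.77 and the peptide gene Ucn3 one of -0.54. Among 18 measured beta cell transcription factor genes, Myt1 alone was at least 2-fold higher (log2 ratio 1.19), and the list median was -0.052. Pdx1 was 446 and 348 in its brighter probe set and had a log2 ratio of 0.34 in its other one. Alpha cell markers (median -0.12 over 11 genes), delta and PP cell markers (median -0.10 over 6 genes), insulin granule exocytosis genes (median -0.034 over 23 genes) and proinsulin processing genes (median -0.048 over 15 genes) all lay within the range of random lists. In the alpha cell list only the amino acid transporter gene Slc38a5 passed 2-fold (log2 ratio 1.41). Of the 8 measured genes of the progenitor and dedifferentiation list, Aldh1a3 and Cck were at least 2-fold higher and Prom1 at least 2-fold lower, with a list median of -0.016 and a mean of 0.68.

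Of 39 lists with enough measured genes, 2 stood apart on the higher side and 10 on the lower side. For lists of independently varying genes, 1.95 would be expected by chance. Genes of 1 list can vary together between preparations, and some lists share genes, so the number to expect for these lists is not known. The lists on the higher side were lactogen response genes and macrophage and dendritic cell markers. The lactogen list, made of genes that respond to prolactin and growth hormone signalling in islets, had 6 of 12 measured genes at least 2-fold higher and none 2-fold lower, with 8 above and 4 below 0. Its median log2 ratio was 0.89, above all 10000 random lists. Ivd, which encodes an enzyme of leucine breakdown, went from 196 to 730, Neb from 31.1 to 93.6, Cish, a feedback inhibitor of cytokine signalling, from 162 to 487 and Fam151a from 234 to 608. Tph1, named here after its value was seen because it encodes the serotonin-synthesising enzyme best known from this response, was 274 and 255. Without a floor and with a pseudocount of 16, the median was 0.48.

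Macrophage and dendritic cell markers had a median log2 ratio of 0.56, above all random lists, with 22 of 23 measured genes above 0 and 4 at least 2-fold higher. Mrc1 went from 24.5 to 131, the complement gene C1qb from 49.1 to 114 and Tyrobp from 45.1 to 94.2, and Fcer1g had a log2 ratio of at least 1.26. Lymphocyte markers had a median of 0.20 over 8 genes, within the range of random lists. Endothelial markers (median -0.10 over 18 genes), fibroblast, stellate and smooth muscle markers (median -0.021 over 17 genes) and Schwann cell and neuron markers (median 0.15 over 11 genes) also lay within it.

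Exocrine acinar cell markers were lower, with a median log2 ratio of -1.04 over 24 genes, below all random lists. In this list 13 genes were at least 2-fold lower and 1, Prss3, was at least 2-fold higher. Among the lower genes of the list, the Reg genes Reg2, Reg3b and Reg1 had the largest ratios, with Reg1 at 1709 in control and 608 in knockout-labelled islets. Acinar transcripts made up some of the brightest signals of both preparations, as shown by the elastase gene Cela3b, named for its brightness after its value was seen, at 8913 and 5590. Duct cell markers were lower by a smaller amount (median -0.28 over 10 genes, 0.56th percentile). Car2 was at least 2.66-fold lower and Krt8 had a log2 ratio of -0.40.

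Genes of the hypoxia response and of glycolysis were lower together. The hypoxia list had a median log2 ratio of -0.67 over 21 genes, 20 of them below 0 and 4 at least 2-fold lower. These were the prolyl hydroxylase gene Egln3 (from 70.2 to 23.4), the collagen prolyl hydroxylase gene P4ha2 (from 524 to 217), the adrenomedullin gene Adm (log2 ratio -1.18) and the hexokinase gene Hk2 (from 56.1 to 28.0). The glycolysis list had a median of -0.54 over 20 genes, 18 of them below 0. Slc2a3 and Slc2a1, both glucose transporter genes, had log2 ratios of -0.99 and -0.77, and Aldoc, an aldolase gene, one of -0.96. The knockout-labelled signal of Slc2a3 was 23.4, next to the floor of 21.7. None of its 3 other probe sets was above the floor on both arrays. Both medians lay below all random lists. The lists share 6 genes, and the 14 glycolysis genes outside the hypoxia list had a median of -0.45. These 14 were set apart by list membership alone. Their median therefore does not show a change of glycolysis genes apart from the hypoxia response. Acinar markers were lower and macrophage markers higher on the same array.

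**Figure D3:**
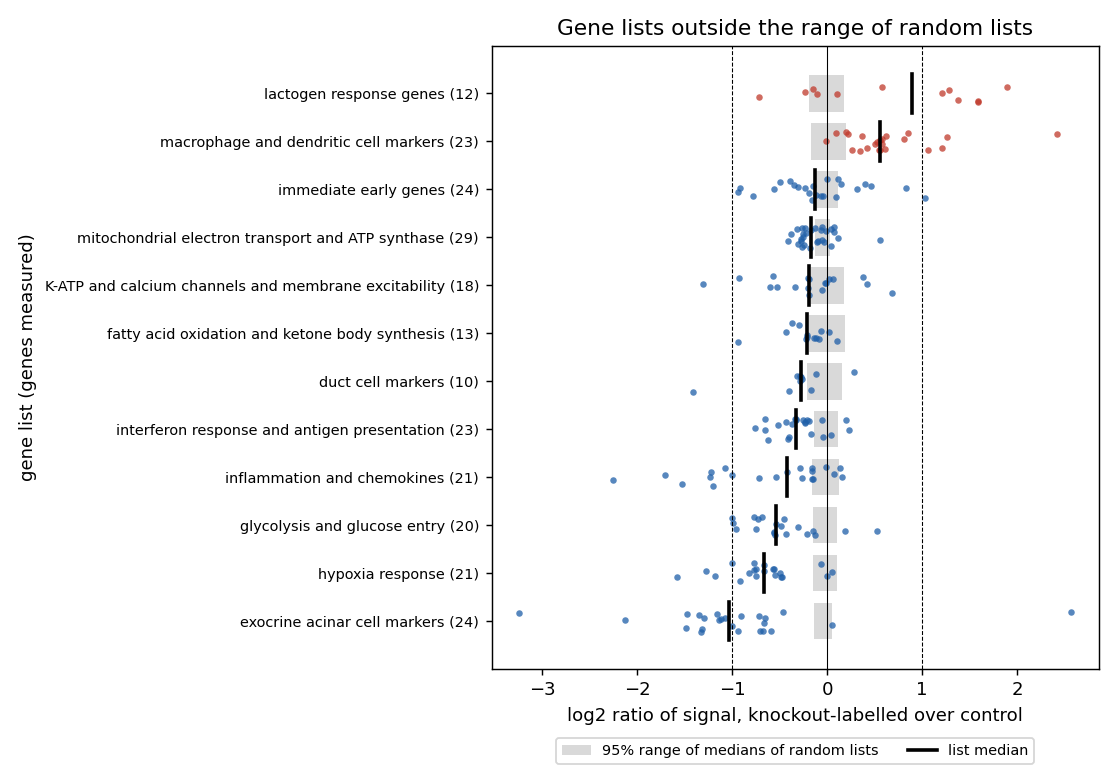
Log2 ratio of signal, knockout-labelled over control (x), for every measured gene (points) of the 12 lists that stood apart (y, number of genes measured in brackets). Black bars are list medians, grey bands hold the central 95% of the medians of 10000 random lists matched on signal, and dashed lines mark 2-fold. The medians run from -1.04 for acinar markers to 0.89 for lactogen response genes.

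Inflammation and chemokine genes were lower as well, with 8 of 21 measured genes at least 2-fold lower, none 2-fold higher and a median log2 ratio of -0.42, below all random lists. Besides Cxcl1 and Cxcl5 these included the cytokine gene Il6 (from 400.4 to 138) and the NF-kappaB inhibitor gene Tnfaip3 (from 329 to 140). The median was -0.26 without a floor and with a pseudocount of 16, and the list mean was -0.66. Interferon response and antigen presentation genes had a median of -0.33 over 23 genes, 20 of them below 0 and none at 2-fold. Ifih1 had a log2 ratio of -0.77, Mx1 one of -0.66 and Oas1a one of -0.63. For Ddx58 the value was -0.66, with another probe set at 0.24. With the mean over all probe sets of a gene the interferon median was -0.21. Macrophage markers, which can carry inflammatory transcripts, were higher on the same array.

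The remaining lists that stood apart did so by small amounts and not under every setting. Mitochondrial electron transport and ATP synthase genes had a median of -0.17 over 29 genes, none at 2-fold, with Atp5a1 at -0.41 and Ndufs4 at 0.56. It was -0.082 with quantile normalization and -0.090 with loess, and with the mean over all probe sets it was -0.082 and no longer stood apart. Cpt1a, which admits fatty acids to mitochondria, was at -0.94 in its brightest probe set and at -0.63 and 0 in its 2 other measured ones. It belongs to the fatty acid oxidation and ketone body genes, whose list median was -0.21 over 13 genes. That list no longer stood apart with quantile normalization (-0.20), loess (-0.19) or the mean over all probe sets (-0.12). Potassium and calcium channel and excitability genes had a median of -0.19 over 18 genes, 13 of them below 0 and 5 above. The potassium channel gene Kcnk3 was at least 2.47-fold lower, Itpr3 was at -0.93 and Scn3a at 0.69. The ATP-sensitive potassium channel genes Kcnj11 (0.42) and Abcc8 (0.056), named after their values were seen, were not lower. The channel list no longer stood apart with floors at the 30th (-0.12) and 70th percentile (-0.10) or without a floor (-0.13). Immediate early genes had a median of -0.13 over 24 genes, with Dusp4 at 1.03 and Egr1 at -0.94, and no longer stood apart under 6 of the alternatives.

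For gluconeogenesis and glucose release genes the list median was 0.078 over 10 genes, within the range of random lists. Fbp1 alone was at least 2-fold higher, and Ppargc1a, a transcriptional coactivator gene, was lower (log2 ratio -1.40). Ppargc1a went from 63 to 23.8, next to the floor of 21.7. None of its 4 other probe sets was above the floor on both arrays. Fbp2, the muscle form of the enzyme, had a log2 ratio of 0.50. Endoplasmic reticulum stress genes were close to equal, with a median of 0.0017 over 31 genes, none at 2-fold and the largest ratios at -0.25 (Hyou1), -0.24 (Atf3), 0.22 (Sel1l) and 0.21 (Pdia4). Lists that also did not stand apart were pyruvate and citric acid cycle genes (median -0.085), cholesterol and fatty acid synthesis genes (0.062), receptor genes (0.073), oxidative stress genes and metallothioneins (-0.099), heat shock proteins (-0.068), apoptosis and p53 targets (-0.045), cell cycle genes (-0.10), cyclins and growth regulators (-0.16), ribosomal proteins (-0.086), genes normally kept low in beta cells (-0.21), genes under ZBTB20 control in liver (-0.18) and ZBTB family members (-0.021). Within these, Txnip, a glucose-responsive inhibitor of thioredoxin, had a log2 ratio of 1.96 and the purinergic receptor gene P2ry1 one of 1.77. The Hsp70 genes Hspa1a and Hspa1b, near-identical copies, had ratios of -1.23 and -1.16. Igf2 was at -1.35, with a knockout-labelled signal of 26.2 against a floor of 21.7. The list of genes under ZBTB20 control in liver was not split by the direction of that control. Its median could therefore hide opposite changes and does not show whether such genes responded.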

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

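Counts of genes followed the floor and the size limit. The number of genes at least 2-fold higher and lower was 695 and 638 with the floor at the 30th percentile and 96 and 64 with the floor at the 70th percentile. It was 814 and 732 at a limit of 1.5-fold, and 51 and 17 at a limit of 3-fold. The other scalings moved the median of all genes by 0.01 or less on the log2 scale. All 69 named genes at 2-fold or more kept their sign under every alternative that measured them, but 40 of 55 stayed at 2-fold with the floor at the 70th percentile and 55 of 69 without a floor. The Zbtb20 median stayed between -0.080 and -0.056. Glycolysis, hypoxia, inflammation, interferon, acinar, duct, lactogen and macrophage lists stood apart in the same direction under every alternative tried. Mitochondrial genes no longer did with the mean over all probe sets (-0.082) or the list mean (-0.13), and their median was also smaller, though still apart, with quantile normalization (-0.082) and loess (-0.090). Fatty acid oxidation genes no longer did with quantile normalization (-0.20), loess (-0.19) or the mean over all probe sets (-0.12), nor channel genes with floors at the 30th (-0.12) and 70th percentile (-0.10) or no floor (-0.13). Immediate early genes no longer did with the floor at the 30th percentile (-0.13), no floor (-0.13), the mean over all probe sets (-0.10), without _x_at and _s_at probe sets (-0.11), with the list mean (-0.10) or with unmatched random lists (-0.13). The number of lists standing apart on the higher side went from 2 to 4 with the floor at the 70th percentile and to 6 with list means. Of the 27 lists within the random range, 9 stood apart under at least 1 alternative, most often liver genes under ZBTB20 control (4 alternatives, lower) and heat shock proteins (3 alternatives, lower). Means follow single large ratios such as those of Fbp1, Npy and Aldh1a3, and for 8 lists median and mean had opposite signs. Beyond that the cause was not tested. No paired analysis was possible because each group had 1 array, and no replicate could be left out. Weak signals limit the precision: 126 of the 301 genes at 2-fold on both arrays had a mean signal of 67 or less.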

Other observations

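The sex-linked list mixes X-linked and Y-linked genes, which a sex difference would move in opposite directions, so its median log2 ratio of -0.057 over 7 genes decides nothing. Xist, the female-specific regulator of X inactivation, had signals of 434 and 328 in control and knockout-labelled islets in its brightest probe set, and its other probe sets went the other way (log2 ratios of 0.11 and 0.31). Of the Y-linked genes, Eif2s3y had signals of 106 and 63.8, Kdm5d, named after its value was seen, 33.7 on both arrays and Uty 34.4 and 46.2 in 1 probe set and 44.2 and 29.8 in another. Of the adipocyte list only 3 genes were measured. Lpl was at 1911 and 1112 and, both named after their values were seen, Fabp4 at 570 and 677 and Retn at 26.6 and 6.8. Of the erythroid list 1 gene was measured. Among 1722 probe sets without a gene name that were above the floor on both arrays, 28 were at least 2-fold higher and 22 at least 2-fold lower. The largest were 1445546_at (from 22.2 to 176) and 1429344_at (from 51.9 to 195) on the higher side, and 1457256_x_at (from 74.9 to 26.3) and 1440977_at (from 132 to 46.5) on the lower side.

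In the 3 patterns below, the tests on weak signals and on signal-dependent bias were set before their results were seen, and the others after. In each pattern the genotype itself stays open, because genotype, preparation and array cannot be separated with 1 array per group.

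Lactogen response genes were higher in knockout-labelled islets. Weak signals do not account for this. With the floor at the 70th percentile, the median was 0.88 over the 10 members still measured, against an upper limit of 0.18 for random lists. A gene, in the list or drawn at random, was kept if it passed that floor on 1 or both arrays. Extra macrophages stay open, since the list median exceeded that of the macrophage markers by 0.34, with a 95% bootstrap interval over genes from -0.69 to 0.94. Of the 12 members, 6 lay above the limit of 1.06, 1 SD over the macrophage median, as did 4 of the 23 macrophage markers. Another candidate explanation is growth hormone made by the Cre driver transgene, since some insulin promoter Cre lines carry a human growth hormone minigene. This stays open too: 6 of 12 list members were at least 2-fold higher and 8 were above 0, but 4 were below 0 (all named after their values were seen: Tph1, which such a hormone would raise, at -0.11, Socs3 at -0.72, Bcl6 at -0.24 and Ccnd2 at -0.16). The control array is titled wildtype, but the sources used here name no driver and do not state whether the controls carried Cre.

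Acinar markers were lower in knockout-labelled islets. A different share of islet cells in the 2 preparations would move all other cell types alike only if none of them lay inside the islets. The macrophage and acinar medians were 1.59 apart on the log2 scale, so these 2 cell types did not move by 1 factor. Whether the macrophages came from inside the islets was not measured, so this gap does not exclude a different share of islet cells. Less acinar tissue carried along would lower acinar transcripts by 1 factor, and the 20 markers other than the Reg genes and Prss3 had an SD of 0.38 around a median of -0.97, under the limit of 0.41, with 19 of them below 0. The Reg genes and Prss3 were set apart after their ratios were seen, which by itself narrows the SD. Less acinar tissue therefore stays possible for these 20 markers, but the SD does not decide it. The exception among the 20 was Bhlha15, a transcription factor gene named after its value was seen. Its log2 ratio of 0.055 lay above the upper limit of -0.22, 2 SDs over the median of -0.97. Less acinar tissue does not account for Prss3 either, which lay 3.54 above the other markers. Transcripts of the trypsinogen paralog Prss2, named after its value was seen, would not raise it, since Prss2 was lower (log2 ratio -1.14). Those of another paralog or a difference in the cells themselves may remain. The Reg genes stay open: their median differed from that of the other markers by -1.15, but only Reg2 and Reg3b, already seen among the largest ratios, lay below the limit of -1.73, and Reg1 did not.

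Hypoxia response genes were lower in knockout-labelled islets. A signal-dependent bias between the arrays does not account for this, since the list median was -0.65 after loess against a lower limit of -0.12 for random lists. A difference in oxygen supply between the 2 preparations, as islet size or culture density could give, was not put to a test that decides. The 15 hypoxia genes outside the glycolysis list had a median of -0.67, but they are most of the list that showed the pattern. A change of the same genes in beta cells through the loss of Zbtb20 would look alike, and no value here separates the 2.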
